A study of Thermus scotoductus SA-01 with 17 samples.

How the data were processed

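RNA sequencing was carried out on Thermus scotoductus SA-01 cultures grown at 65 °C in a microwave digestor (300 W, 2.45 GHz) or a convective incubator and sampled at 8, 14 and 24 h, per the labels' protocols. Each Teflon vessel held 60 mL of medium with a 1% inoculum and 3 mL aliquots were taken. RNA was extracted with a column kit and DNase, depleted of rRNA with Ribo-Zero and made into libraries with the NEBNext Ultra RNA kit, per the labels' protocols. Whether strand was kept is not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart.

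The deposited count table holds whole-number read counts per locus tag and library, made by the authors with Trimmomatic, Bowtie2 and HTSeq per the submitters' processing notes, whose versions are not given in the sources used here. The authors' deposited tables, 1 per time, hold log2 RPKM values per library normalised with cqn, a method that adjusts for GC content and gene length, per the file headers and sheet names. They also hold an adjusted p-value per gene, and the authors kept genes at about 0.05, per the sheet names, with the test not given in the sources used here. The 14 h table also has a deposited ratio column, which for 1048 of 1048 genes equals, within 1%, the microwave mean of the log2 values divided by the convective mean. It is therefore not a fold change and was not used here. Fold changes here come from the counts.

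The count table has 2518 locus tags, 2506 on the chromosome and 12 on the plasmid, and 5 closing lines of HTSeq for reads given to no gene. Those lines stayed out of library sizes and tests. Reads outside annotated genes made up 2.49% to 12.3% of all reads, reads overlapping more than 1 gene 2.24% to 9.04%, and low-quality alignments 1.92% to 67.5%, the last in microwave 14 h replicate 2. The line for reads with more than 1 alignment is 0 in all libraries, so counts of near-identical copies such as tuf, lon, rRNA and transposase genes are uncertain. Of the locus tags 53 have neither symbol nor product, 4 of them at least 1000 bp long and 49 under 130 bp, and they were treated as rRNA and tRNA genes in an alternative. For 113 locus tags the symbol stands in the product column and was read from there. Coordinates are those of the count table's own annotation of the SA-01 chromosome. Symbols and products are as in that table, where cas1 carries the product name of Cas2.

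Libraries were grouped by heating mode and time from their titles. The 2 convective 8 h columns carry numbers that differ from those in the titles and are named by depth, deeper and shallower. Groups, comparisons, tests, gene lists and the rule for named genes were fixed before the data were examined. Counts were fitted with edgeR 4.0.16 in R 4.3.3, as 1 quasi-likelihood model over all 17 libraries with 1 mean per group, TMM scaling and the default expression filter, which left 2461 genes. Comparisons were microwave against convective at each time, the change of that difference between times, and the change between times within each heating mode. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The SE of a log2 fold change is its size divided by the square root of the F statistic. Levels are TMM-scaled CPM, given as mean ± SD over libraries, and log CPM used a prior count of 2.

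Gene lists were tested with camera on voom values (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 33 lists with at least 4 tested genes, and again with an estimated correlation. They were also tested with fry, which asks whether a list's genes move one way on balance and, unlike camera, makes no comparison with other genes. The lists covered heat shock, cell division, cell wall and rod shape, compatible solutes, oxidative stress, SOS and DNA repair, ribosomal proteins, translation, RNA polymerase, ATP synthase, NADH dehydrogenase, cytochromes, the TCA cycle, glycolysis, glutamate to arginine, branched-chain, and histidine and aromatic amino acids, amino acid and sugar transport, carotenoids, pili, CRISPR-Cas, mobile elements, cobalamin, fatty acid synthesis, fatty acid oxidation, phenylacetate, purines and pyrimidines, sulfur, nitrate, metals, regulators and toxins. They were built from words in products and symbols, so some members lie outside the list's theme. The heat shock list holds the nitrate reductase chaperone narJ and the cell wall list a gamma-glutamyltranspeptidase. The nitrate list holds a gene annotated as a ferredoxin-nitrite reductase and the fixed genes a folylpolyglutamate synthase.

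Genes named at each heating comparison are the fixed genes, the 8 highest and 8 lowest called genes with a known product, a mean of at least 50 counts and no overlap between groups, and up to 3 members of each list past its threshold. For changes of the difference the 3 highest and 3 lowest were named, and for times the 4 highest and 4 lowest.

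Library totals ranged from 895861 to 6058136 gene counts. The common dispersion gave a coefficient of variation of 26.4% between libraries of a group in the fit of all 17. In fits of 1 time alone it was 12.1% at 8 h, 30.9% at 14 h and 28.9% at 24 h. The fit was tested on simulated counts with known changes. Of genes changed by 1 log2 unit, 52% were recovered at 8 h (2444 genes run, 7 false calls), 56.6% at 14 h (2439 genes, 5 false calls) and 62% at 24 h (2444 genes, 11 false calls). Of genes changed by 2 log2 units, 95%, 96% and 94% were recovered. The simulated libraries had 1 spread per gene at all times, few changed genes and no library standing apart. These rates therefore need not hold for the real data.

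Alternatives were DESeq2 1.42.0, RLE scaling, no expression filter, a fit of the compared libraries alone, a replicate block, a minimum log2 change of 1, leaving out the rRNA and tRNA rows, and leaving out each library. Those chosen after the data were seen left out the 3 replicates standing apart or the 3 libraries with over 2% of counts on unannotated rows, used the column number as the block, or took symbols as the columns stand. A correction for GC content and length needs the genome sequence and was not run. The deposited log2 RPKM values were used only to compare gene directions with the counts.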

Results

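RNA was sequenced from Thermus scotoductus SA-01, a thermophilic bacterium that can respire oxygen or nitrate, grown at 65 °C in rich medium either in a microwave digestor (2.45 GHz, 300 W) or in a convective incubator. Cultures were sampled 8, 14 and 24 h after inoculation. The labels place 8 and 14 h in log phase and 24 h in stationary phase, and they describe the cells as elongated for the microwave 24 h group. The count table held 17 libraries in 6 groups, with 2 libraries for convective 8 h and 3 for each other group. Total gene counts were 895861 in the shallower and 6058136 in the deeper convective 8 h library. They ranged from 1608049 to 2087107 in microwave 8 h, from 2471205 to 3635147 in convective 14 h, from 1683343 to 3969854 in microwave 14 h, from 3485149 to 5143540 in convective 24 h and from 2239125 to 3790053 in microwave 24 h. Of 2518 annotated genes, 2461 had enough counts to be tested. The questions were which genes differed between the heating modes at each time, whether that difference changed with time, and which genes changed over the growth course.

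Replicate 1 stood apart from the other 2 libraries in 3 groups. Its Spearman correlation with the others across genes was at most 0.907 in microwave 14 h, where the others correlated at 0.976. In microwave 24 h it was at most 0.916 against 0.996, and in convective 24 h at most 0.972 against 0.997. Rows with neither symbol nor product, whose 4 longest have the size of rRNA genes, took 23.7% of the gene counts in microwave 14 h replicate 2, 3.88% in microwave 24 h replicate 3 and 2.05% in convective 14 h replicate 3. In the other libraries they took at most 1.29%. The same 3 libraries had the highest shares of low-quality alignments, at 67.5%, 30.0% and 20.1% of all reads, against at most 14.0% elsewhere. Those reads were given to no gene and their origin was not tested, so the shares on unannotated rows may understate rRNA reads. The 10 highest genes held 23.2% ± 9.30 of the gene counts in microwave 14 h and 12.9% ± 0.674 in convective 14 h (SD, n = 3 each). At 24 h they held 22.4% ± 4.48 in microwave and 13.8% ± 0.393 in convective libraries.

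**Figure D1:**
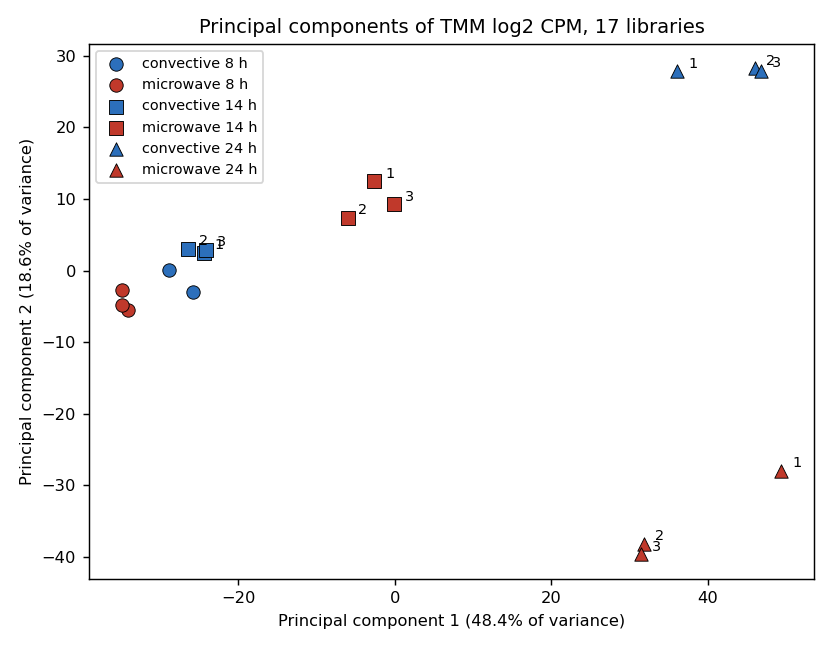
Principal components of log2 CPM (counts scaled to the size of the library) over the tested genes, one point per library, coloured by heating mode and marked by time. The first component took 48.4% of the variance and the second 18.6%. Replicate 1 of convective 24 h and of microwave 24 h lies away from the other 2 libraries of its group.

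At 8 h, genes of nitrite and nitric oxide reduction and of a sugar transporter were lower in microwave-heated cells, and the arginine synthesis genes argG, argH1 and argF were higher. The copper-containing nitrite reductase TSC_c17620, which makes nitric oxide from nitrite, was 55.7-fold lower, at 87.8 ± 11 CPM against 4890 ± 3980 in convective cells (SD, n = 3 and 2; log2 difference -5.80 ± 0.62 SE, adjusted p = 7.66e-05). It lies on the chromosome at 1672608 to 1673963, in the coordinates of the count table. Its neighbours norB and TSC_c17610, both of nitric oxide reductase, were 7.69-fold and 6.88-fold lower. The permease genes TSC_c14820 and TSC_c14830 of a sugar ABC transporter were 13.5-fold and 8.69-fold lower, and its substrate-binding gene TSC_c14810 fell from 1560 ± 173 to 208 ± 48.8 CPM. The molybdopterin oxidoreductase gene TSC_c14620 was 10.7-fold lower. On the higher side, argG and argH1, which turn citrulline into arginine, were 3.46-fold and 3.19-fold higher (adjusted p = 0.00206 and 0.000811), and argF, which makes citrulline, was 3.16-fold higher. The manganese catalase gene TSC_c06390, for hydrogen peroxide removal, was 7.78-fold higher at 653 ± 281 against 84.9 ± 32.0 CPM, and bioY, for biotin uptake, 6.90-fold higher. The gluconate 5-dehydrogenase gene TSC_c11860, the AMP-binding domain gene TSC_c11870 and the hydrolase gene TSC_c13640 were 3.49-fold, 3.25-fold and 3.19-fold higher. The 2 convective libraries differed in the nitrite reductase gene itself, at 2080 CPM in the deeper and 7710 CPM in the shallower. Without the shallower library its log2 difference was -4.56, that of norB -2.04, of TSC_c17610 -2.03 and of TSC_c14620 -2.26, and without the deeper one it was -6.46 for TSC_c17620 and -4.09 for TSC_c14620.

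Some heat shock genes were lower in microwave-heated cells at 8 h. The small heat shock protein genes TSC_c20340 and TSC_c20360, whose products bind unfolding proteins, were 6.66-fold and 6.32-fold lower, and clpB, a disaggregating chaperone, 3.87-fold lower at 124 ± 10.5 against 480 ± 10.1 CPM (adjusted p = 0.00524). Of the list's 28 tested genes 2 were higher, 5 lower and 21 not called, and adjusted over the list alone 4 were higher and 13 lower (camera adjusted p = 0.00128). With an estimated correlation the adjusted p was 0.391. Of the 18 NADH dehydrogenase genes, 4 were lower and none higher, and adjusted over the list alone 8 were lower (camera adjusted p = 6.48e-06, and adjusted p = 0.639 with an estimated correlation). The lowest adjusted p was that of TSC_c14670, annotated as a 39 kDa subunit, at -1.84 ± 0.16 log2 units, with nuoA at -1.16 ± 0.31 and nuoB at -1.23 ± 0.35. Of the 9 nitrate and anaerobic respiration genes 3 were lower, those for nitrite and nitric oxide reductase, in both adjustments, over all genes and adjusted over the list alone (camera adjusted p = 0.00201, and adjusted p = 0.541 with an estimated correlation). Of 24 cell wall and rod shape genes 2 were higher, and the same number adjusted over the list alone (camera adjusted p = 0.024, and adjusted p = 0.541 with an estimated correlation). They were uppS, for the lipid carrier of wall precursors, at 1.02 ± 0.20 and the gamma-glutamyltranspeptidase gene TSC_c12020 at 1.03 ± 0.19, whose enzyme acts on glutathione and not on the wall. The rod shape gene mreD was at 0.56 ± 0.18, not called. Of 18 fatty acid and acetate oxidation genes 3 were higher and 1 lower, and adjusted over the list alone 6 higher and 1 lower (camera adjusted p = 0.0291, and adjusted p = 0.783 with an estimated correlation). The higher ones were the acyl-CoA dehydrogenase genes bcd2 at 1.29 ± 0.27 and TSC_c13020 at 0.68 ± 0.15 and the enoyl-CoA hydratase gene TSC_c13200 at 1.40 ± 0.37.

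Among the genes fixed by name, clpB alone was called at 8 h in the fit of all libraries. The log2 differences of the others were -1 ± 0.38 for dnaK, -1.16 ± 0.38 for a second clpB gene, TSC_c08090, -0.45 ± 0.17 for the main sigma factor rpoD, -0.20 ± 0.52 for groL, -0.10 ± 0.22 for recA, 0.02 ± 0.50 for glnA, 0.13 ± 0.31 for the heat shock repressor gene TSC_c24620 and 0.14 ± 0.14 for mreB. They were 0.20 ± 0.18 for ftsA, 0.31 ± 0.24 for ftsZ, 0.41 ± 0.13 for minD, 0.56 ± 0.17 for the folate gene TSC_c05000, 0.58 ± 0.26 for murA and 0.82 ± 0.27 for the glutamate synthase gene TSC_c20490. In a fit of the 5 libraries of 8 h alone dnaK, TSC_c08090, rpoD, minD, mreD, murA, TSC_c05000 and TSC_c20490 were called as well (adjusted p = 0.000146, 0.000175, 0.0121, 0.0187, 0.0191, 0.0121, 0.0207 and 0.00116). DESeq2 called all of these except murA, and without the deeper convective library TSC_c05000 was called (0.0256).

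In all, 105 genes were higher and 120 lower in microwave-heated cells at 8 h in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 225 of 2461. The count was 344 with DESeq2 and 844 in the fit of the 8 h libraries alone. It was 114 without the deeper and 54 without the shallower convective library, and 113, 121 and 98 without microwave replicate 1, 2 or 3. Without either convective library the catalase gene TSC_c06390 (adjusted p = 0.126 without the deeper, 0.0812 without the shallower), bioY (0.0823 and 0.0812), uppS (0.064 and 0.0644), nuoA (0.0943 and 0.227), nuoB (0.116 and 0.275), TSC_c11860 (0.0706 and 0.233), TSC_c13640 (0.305 and 0.141), TSC_c13020 (0.0555 and 0.175) and TSC_c13200 (0.116 and 0.261) were no longer called. Without the shallower one argF (0.175), TSC_c11870 (0.0772), TSC_c12020 (0.0874), bcd2 (0.152) and the cell wall and fatty acid oxidation lists (0.181 and 0.0993) were not called either. In the fit of the 8 h libraries alone the cell wall and nitrate lists were not called (0.0747 and 0.0512). With fry, which tests whether a list moves one way and does not set it against other genes, the NADH dehydrogenase and fatty acid oxidation lists were not called (0.062 and 0.102), and with symbols as the columns stand the fatty acid oxidation list was not (0.0586). The calls of TSC_c13200, TSC_c13640 and nuoB were also lost without microwave replicate 1 (0.0543, 0.0702 and 0.105), 2 (0.07, 0.0949 and 0.07) or 3 (0.0842, 0.111 and 0.155), those of nuoA without replicate 1 or 3 (0.0756 and 0.127), of TSC_c11860 without 2 or 3 (0.07 and 0.0728) and of TSC_c13020 without 2 (0.0508). With RLE scaling the call of TSC_c13640 was lost (0.0513).

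At 14 h, thiamine synthesis genes were higher in microwave-heated cells, nitrate reductase genes were lower and nitric oxide reductase genes were higher. The cluster thiE, thiS, thiG, TSC_c11830, thiC and thiD, on the chromosome from 1120601 with its neighbour TSC_c11860 ending at 1126027, makes the vitamin's pyrimidine and thiazole parts. In it thiG was 572-fold higher, at 2300 ± 1380 against 3.92 ± 0.901 CPM (SD, n = 3 each; log2 difference 9.16 ± 0.71, adjusted p = 9.93e-07). The oxidoreductase gene TSC_c11830 was 323-fold, thiE 251-fold, thiC 193-fold and thiD 58.5-fold higher, and thiS was at 199 ± 120 CPM against 0.535 ± 0.591, near the floor of the convective libraries. An ABC transporter encoded by TSC_c04280 and TSC_c04290 was 27.6-fold and 17-fold higher. Of the nitrate reductase genes, narG, for the catalytic subunit, was 31.9-fold lower at 25.6 ± 8.00 against 815 ± 549 CPM (log2 difference -5 ± 0.71, adjusted p = 0.000113), narI 86.6-fold and narJ 96.3-fold lower, the last at 1.76 ± 1.04 CPM in microwave libraries. The NarK1 gene TSC_c17470, for nitrate transport, was 45.0-fold lower, the nitrite reductase gene TSC_c17620 21.7-fold, the ferredoxin gene TSC_c14610 15.1-fold, the molybdopterin oxidoreductase gene TSC_c14620 10.8-fold and the periplasmic cytochrome gene TSC_c17520 10.5-fold lower. Of nitric oxide reductase, norB was higher by 1.85 ± 0.38 log2 units, at 13800 ± 2530 against 3820 ± 320 CPM (adjusted p = 0.0016), and TSC_c17610 by 2.23 ± 0.32, at 7780 ± 1390 against 1660 ± 101 CPM, the opposite of 8 and 24 h. Leaving out microwave replicate 3 changed the log2 difference of TSC_c04290 from 4.09 to 3.49, and leaving out convective replicate 1 changed that of thiS from 8.32 to 9.37.

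NADH dehydrogenase genes were higher at 14 h in 17 of 18 cases, with none lower and 1 not called, and adjusted over the list alone in all 18 (camera adjusted p = 1.59e-06, and adjusted p = 0.603 with an estimated correlation). The subunit genes nuoC and nuoD were 5.27-fold and 4.75-fold higher and TSC_c14670 2.40-fold. Sulfur and iron-sulfur genes were higher in 14 of 23 cases, none lower and 9 not called, and adjusted over the list alone in 15 (camera adjusted p = 3.08e-05, and adjusted p = 0.11 with an estimated correlation). Among them the iron-sulfur cluster assembly genes TSC_c17400, iscA and sufE were 6.10-fold, 3.58-fold and 2.48-fold higher. All 7 CRISPR-Cas genes, of a defence system against foreign DNA, were higher in both adjustments, over all genes and adjusted over the list alone (camera adjusted p = 0.00221, and adjusted p = 0.603 with an estimated correlation), with cas1 at 1.02 ± 0.16, TSC_c12480 at 0.96 ± 0.19 and TSC_c12490 at 1.01 ± 0.21 log2 units. Of 54 ribosomal protein genes 1 was higher, 18 lower and 35 not called, the same counts adjusted over the list alone (camera adjusted p = 1.41e-05, and adjusted p = 0.758 with an estimated correlation). The genes rpsB, rplA and rplK were 2.70-fold, 2.68-fold and 2.53-fold lower. Of 35 translation factor and aminoacyl-tRNA synthetase genes 1 was higher, 12 lower and 22 not called, the same counts adjusted over the list alone (camera adjusted p = 0.0224, and adjusted p = 0.62 with an estimated correlation). The elongation factor genes tsf and efp were 3.41-fold and 2.60-fold lower and the glutamyl-tRNA synthetase gene gltX 1.69-fold. The heat shock list went both ways, with 8 higher, 8 lower and 12 not called (camera adjusted p = 0.883), as did the nitrate list, with 3 higher and 5 lower of 9 (0.589). Of the cell wall genes 4 were higher and 8 lower (0.335), and of the fatty acid oxidation genes 1 each way (0.656).

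Among the fixed genes at 14 h, groL, the large chaperonin subunit, fell by 1.67 ± 0.48 log2 units, clpB fell by 1.28 ± 0.34 and the glutamate synthase gene TSC_c20490 fell by 1.34 ± 0.24. The second clpB gene, TSC_c08090, was higher by 1.41 ± 0.35 and murA, which commits precursors to wall synthesis, by 0.72 ± 0.23 (adjusted p = 0.0207). The log2 difference of groL was -2.64 without microwave replicate 1, and its call was lost in a fit of the 6 libraries alone (adjusted p = 0.0681) and without the 3 libraries rich in unannotated rows (0.125). The call of murA was lost without convective replicate 1, 2 or 3 (0.0568, 0.0537 and 0.0588) without microwave replicate 2 or 3 (0.111 and 0.0563), in the fit of the 6 libraries alone (0.0896) and without the libraries rich in unannotated rows (0.214). The others were at 0.00 ± 0.35 for dnaK, 0.01 ± 0.13 for mreB, 0.05 ± 0.15 for TSC_c05000, 0.16 ± 0.16 for ftsA, 0.23 ± 0.16 for rpoD, 0.32 ± 0.19 for recA, 0.42 ± 0.21 for ftsZ, 0.45 ± 0.28 for TSC_c24620, -0.17 ± 0.45 for glnA and -0.19 ± 0.12 for minD. Without microwave replicate 1 glnA, at -1.20 log2 units, and recA, at 0.48, were called (adjusted p = 0.00394 and 0.049). Without the 3 replicates standing apart ftsZ, at 0.54, ftsA, at 0.26, and TSC_c24620, at 0.39, were also called (adjusted p = 0.00186, 0.0403 and 0.0267).

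At 14 h 505 genes were higher and 501 lower in microwave-heated cells, 1006 of 2461. Leaving out the 3 replicates that stand apart, an alternative chosen after the data were seen, gave 1531 genes. Leaving out these replicates gave 35 lower ribosomal protein genes, 17 higher NADH dehydrogenase genes and 7 higher CRISPR-Cas genes. It also gave 13 lower phenylacetate and aromatic degradation genes, against 1, and 17 lower amino acid and peptide transport genes, against 7. Cell wall genes were then 9 higher and 8 lower, against 4 and 8, fatty acid oxidation genes 1 and 6, against 1 and 1, and all 6 ATP synthase genes were higher, against 2. Without the 3 libraries rich in unannotated rows, which leaves fewer libraries, 743 genes were called at 14 h. Of the NADH dehydrogenase genes 9 were then higher and of the CRISPR-Cas genes 5, with none lower, and 18 ribosomal protein genes were lower with none higher. In microwave replicate 1 the NADH dehydrogenase genes lay a median of -1.29 log2 units from the other 2 microwave libraries, the CRISPR-Cas genes -0.43, the ribosomal protein genes -0.39 and the phenylacetate and aromatic degradation genes 5.50.

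**Figure D2:**
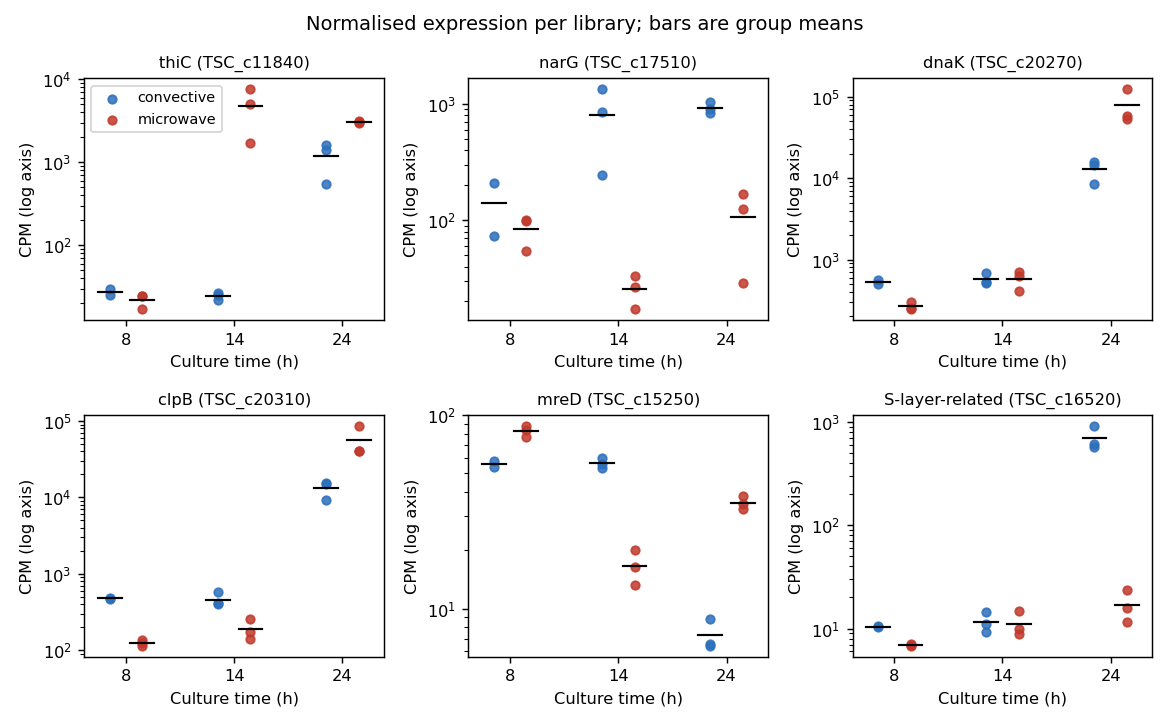
CPM per library on a log axis for thiC, narG, dnaK, clpB, mreD and the surface-layer related gene TSC_c16520, with convective and microwave libraries side by side at 8, 14 and 24 h. Points are libraries and bars are group means.

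At 24 h, when microwave-heated cells are described as elongated, the chaperone genes dnaK and clpB and most genes of the ribosomal protein and wall lists were higher in them, and most genes of the pilus list, a 4-hydroxyphenylacetate cluster and nearly all genes of a stretch that holds a surface-layer related gene were lower. The chaperone gene dnaK was 6.05-fold higher, at 78200 ± 39000 against 12900 ± 3810 CPM (SD, n = 3 each; log2 difference 2.60 ± 0.37, adjusted p = 4.01e-05), and clpB 4.23-fold higher. The sigma factor gene rpoD was 3.73-fold higher, at 3650 ± 104 against 979 ± 189 CPM (adjusted p = 5.22e-07). The surface-layer related gene TSC_c16520 was 41.0-fold lower, at 16.9 ± 6.04 against 699 ± 187 CPM (adjusted p = 1.66e-08). It lies within a stretch from TSC_c15880 to TSC_c16670 in which 76 of 77 tested genes were lower. The ends of the stretch were set by runs of genes each lower by at least 2 log2 units in this same comparison, so most were lower by that choice. The 4-hydroxyphenylacetate degradation genes hpaB, hpaG, hpaE and hpaD and the phenol hydroxylase gene TSC_c10460 beside them were 27.3-fold, 26.5-fold, 24.6-fold, 22.1-fold and 21.7-fold lower, together with dapA2 in the same cluster at 24.4-fold. The nitrite reductase gene TSC_c17620 was 25.4-fold lower at 13.5 ± 5.62 against 346 ± 218 CPM, with a log2 difference of -4.67, or -4.07 without convective replicate 1. The gene TSC_c11790 was 14.0-fold higher at 8670 ± 825 against 620 ± 194 CPM. It is annotated as a ferredoxin-nitrite reductase and lies beside sulfate assimilation genes, and its role was not tested. Also higher were the ApbE family gene TSC_c02550 (24.8-fold), the virulence-associated protein E gene TSC_c10160 (23.6-fold), azlC (20.2-fold) and the methyltransferase gene TSC_c02320 (18.1-fold). The neighbours TSC_c12600, an AAA+ ATPase gene, TSC_c12630, a glycosyl transferase gene, and TSC_c12640, a membrane protein gene, were higher by 4.40, 5.39 and 4.33 log2 units, and without microwave replicate 1 by 2.94, 3.23 and 2.56. In that replicate TSC_c12630 was at 1360 CPM, and at 122 and 116 CPM in the other 2.

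Of 24 cell wall and rod shape genes, 15 were higher, 2 lower and 7 not called at 24 h, the same counts adjusted over the list alone (camera adjusted p = 0.00988, and adjusted p = 0.636 with an estimated correlation). Genes of lateral wall growth were among them, with mreD 4.80-fold, mrdA, for penicillin-binding protein 2, 4.13-fold and mreC 3.33-fold higher. In convective cells mreD fell from 56.3 CPM at 14 h to 7.27 at 24 h. In microwave cells it was at 83.0, 16.6 and 35.2 CPM at 8, 14 and 24 h, so its 24 h level lay under that of 8 h. The levels of mrdA and mreC went the same ways. The gene murA was 2.65-fold higher (adjusted p = 0.000126), while mreB, the filament former of the same machinery, was at -0.03 ± 0.13 log2 units, not called. Of 54 ribosomal protein genes 41 were higher, 4 lower and 9 not called, and adjusted over the list alone 42 higher and 4 lower (camera adjusted p = 4.67e-05, and adjusted p = 0.747 with an estimated correlation). The genes rplT, rpsM and rplA were 4.09-fold, 2.85-fold and 2.41-fold higher. Of 20 type IV pilus and competence genes, for twitching motility and DNA uptake, 2 were higher, 13 lower and 5 not called, the same counts adjusted over the list alone (camera adjusted p = 0.00988, and adjusted p = 0.636 with an estimated correlation), with pilN 4.14-fold, pilO 3.58-fold and pilM 3.34-fold lower. Of 18 NADH dehydrogenase genes 10 were higher, 1 lower and 7 not called, the same counts adjusted over the list alone (camera adjusted p = 0.0389, and adjusted p = 0.769 with an estimated correlation), led by TSC_c14670 at 5.03-fold, nuoN at 4.64-fold and nuoL at 3.76-fold. Of 28 histidine and aromatic amino acid synthesis genes 15 were higher and none lower, the same adjusted over the list alone (camera adjusted p = 0.0389, and adjusted p = 0.653 with an estimated correlation), such as aroC1 at 2.43-fold, trpA at 2.31-fold and the anthranilate synthase gene TSC_c14010 at 2.08-fold. Of 9 nitrate and anaerobic respiration genes 1, TSC_c11790, was higher and 5 were lower, the same adjusted over the list alone (camera adjusted p = 0.0468, and adjusted p = 0.653 with an estimated correlation), with TSC_c17610 12.5-fold and norB 7.68-fold lower. The heat shock list had 12 higher, 3 lower and 13 not called (camera adjusted p = 0.327).

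The NADH dehydrogenase and nitrate lists were not called without convective replicate 1 (adjusted p = 0.099 and 0.0511) or microwave replicate 1 (0.232 and 0.212), and the nitrate and the histidine and aromatic lists were not called in a fit of the 24 h libraries alone (0.0746 and 0.0511). With symbols as the columns stand the NADH dehydrogenase and nitrate lists were not called (0.417 and 0.181). In microwave replicate 1 the ribosomal protein genes lay a median of -1.27 log2 units from the other 2 microwave libraries, 53 of 54 of them lower, and the nitrate and anaerobic respiration genes -1.28, 8 of 9 of them lower, in the direction of that list's call. The ATP synthase genes lay 1.46 and the branched-chain amino acid synthesis genes 0.69 log2 units from them, 9 of 10 of the latter higher. Without the 3 replicates that stand apart 48 ribosomal protein genes were higher and 3 lower, 14 wall genes were higher and 13 pilus genes lower, and the NADH dehydrogenase and nitrate lists were not called (0.135 and 0.366). At 24 h the other lists called at an earlier time had 10 higher and 9 lower of 35 translation genes (camera adjusted p = 0.858), 1 higher and 4 lower of 7 CRISPR-Cas genes (0.383), 10 higher and 5 lower of 23 sulfur and iron-sulfur genes (0.458) and 5 higher and 2 lower of 18 fatty acid oxidation genes (0.733).

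Among the other fixed genes at 24 h, the glutamate synthase gene TSC_c20490 was 4.55-fold higher, at 4530 ± 1230 against 995 ± 271 CPM, and glnA, for glutamine synthetase, 5.14-fold lower, at 375 ± 84.2 against 1930 ± 551 CPM (adjusted p = 0.000671). The folate gene TSC_c05000 was 1.63-fold higher. The division gene ftsZ, whose product forms the septal ring, was higher by 0.65 ± 0.22 log2 units (adjusted p = 0.0201), and that call was lost without microwave replicate 1 (0.113), without convective replicate 1 (0.0852) and in a fit of the 24 h libraries alone (0.114). Without the 3 replicates standing apart ftsZ was at 0.20 log2 units, not called (0.22). Other division genes were at 0.20 ± 0.16 for ftsA and 0.16 ± 0.12 for minD, not called. Nor were groL at 0.88 ± 0.47, TSC_c08090 at 0.69 ± 0.35, the heat shock repressor gene TSC_c24620 at 0.60 ± 0.27 and recA at 0.00 ± 0.19, although TSC_c24620 was called without microwave replicate 2 or 3 (0.031 and 0.0232). In all 737 genes were higher and 620 lower in microwave-heated cells at 24 h, 1357 of 2461.

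**Figure D3:**
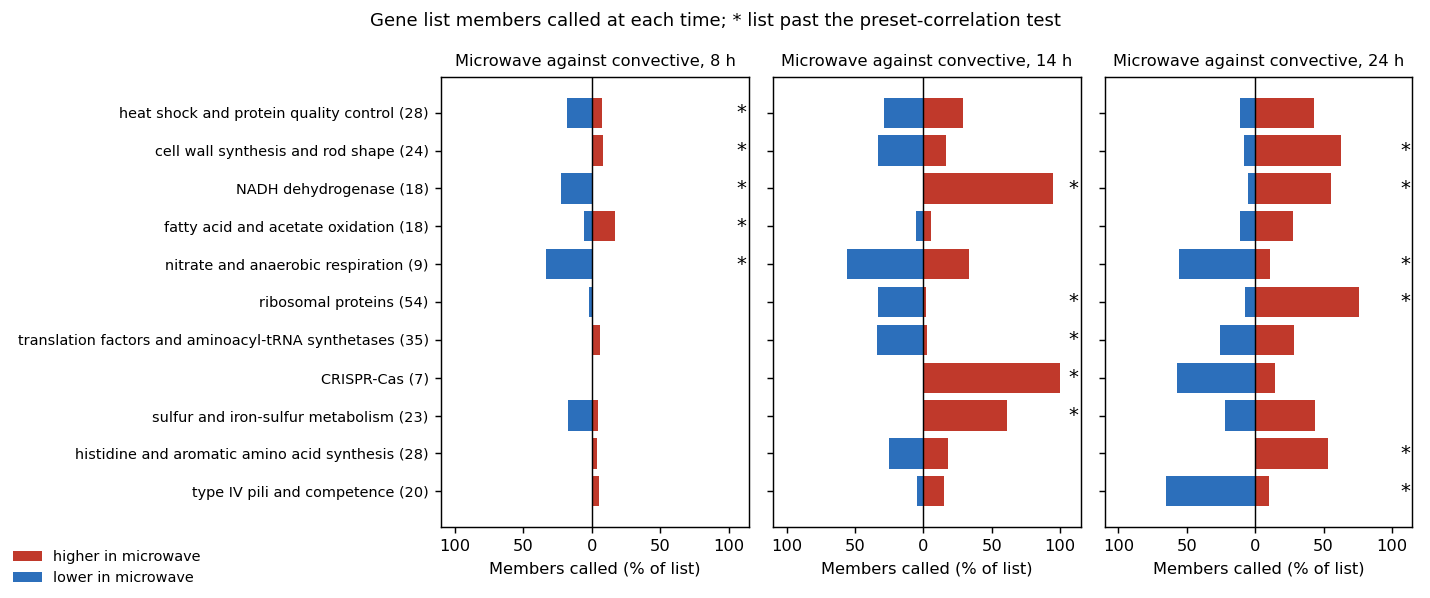
Share of each list's genes called higher (right) and lower (left) in microwave-heated cells, for the lists that passed camera's threshold at any time, with panels for 8, 14 and 24 h. List sizes are in brackets, and an asterisk marks a list past the threshold at that time.

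The remaining lists passed camera's threshold at no time, with adjusted p from 0.051, for RNA polymerase and sigma factors at 24 h, to 0.998. The called genes are given as higher and lower at 8 h, then at 14 h, then at 24 h. Of 18 cell division genes they were 2 and 2, 5 and 2, 5 and 1. Of 5 compatible solute genes they were 0 and 1, 1 and 3, 3 and 0, of 15 oxidative stress genes 3 and 1, 5 and 1, 1 and 6, and of 25 SOS and DNA repair genes 0 and 1, 6 and 6, 8 and 4. RNA polymerase and sigma factors, 5 genes, had 0 and 0, 0 and 3, 4 and 0, and ATP synthase, 6 genes, 0 and 0, 2 and 0, 1 and 0. Cytochromes and terminal oxidases, 27 genes, had 0 and 1, 7 and 1, 4 and 10. The TCA cycle, 20 genes, had 0 and 0, 6 and 3, 8 and 5, and glycolysis, 17 genes, 0 and 0, 4 and 3, 4 and 2. Glutamate, glutamine, proline and arginine genes, 27 in number, had 3 and 0, 2 and 12, 11 and 11. Branched-chain amino acid synthesis, 10 genes, had 0 and 0, 1 and 2, 2 and 2. Amino acid and peptide transport, 25 genes, had 2 and 0, 3 and 7, 5 and 4, and sugar transport, 16 genes, 1 and 3, 3 and 5, 4 and 9. Carotenoid and isoprenoid synthesis, 10 genes, had 0 and 1, 2 and 3, 1 and 3, and mobile elements, 25 genes, 0 and 2, 11 and 4, 14 and 5. Cobalamin synthesis, 10 genes, had 0 and 0, 2 and 1, 5 and 1, and fatty acid synthesis, 13 genes, 2 and 0, 3 and 6, 3 and 5. Phenylacetate and aromatic degradation, 18 genes, had 0 and 0, 1 and 1, 4 and 6, and without the 3 replicates standing apart 3 and 13 at 14 h and 10 and 7 at 24 h. Purine and pyrimidine synthesis, 26 genes, had 1 and 2, 5 and 4, 5 and 8. Metal uptake and efflux, 32 genes, had 1 and 3, 13 and 5, 12 and 8. Regulators and two-component systems, 97 genes, had 2 and 6, 22 and 22, 28 and 22, and toxin and hibernation genes, 14 in number, 1 and 1, 3 and 2, 2 and 6. Without the 3 replicates standing apart the balance at 24 h was another for ATP synthase (1 and 4), the TCA cycle (5 and 9), glycolysis (3 and 6), branched-chain amino acid synthesis (1 and 6) and amino acid and peptide transport (4 and 10). At 14 h it was, among others, for SOS and DNA repair (10 and 6). Without the 3 libraries rich in unannotated rows it was at 14 h for lists such as SOS and DNA repair (4 and 2), cell division (2 and 2) and purine and pyrimidine synthesis (0 and 3). Where a count at 8 h is 0 on both sides, edgeR called none of the list's genes, and over all genes 586 had an unadjusted p under 0.05 and DESeq2 called 344.

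The difference between heating modes itself changed with time. For 757 genes it differed between 14 and 8 h (361 more positive at 14 h, 396 more negative), for 1292 between 24 and 14 h (684 and 608) and for 997 between 24 and 8 h (538 and 459). From 8 to 14 h the NADH dehydrogenase difference became more positive for 17 of 18 genes, also adjusted over the list alone (camera adjusted p = 5.73e-09, and adjusted p = 0.411 with an estimated correlation). The ribosomal protein difference became more positive for 44 of 54 genes from 14 to 24 h, and adjusted over the list alone for 45 with 1 more negative (camera adjusted p = 3.88e-08, and adjusted p = 0.685 with an estimated correlation). In log2 units the change from 14 to 24 h was 2.69 ± 0.23 for rplA, 4 ± 0.25 for mreD, 3.36 ± 0.49 for clpB and 2.59 ± 0.50 for dnaK. Other lists past camera's threshold for 14 against 8 h were CRISPR-Cas (4 genes more positive), sulfur and iron-sulfur (9), metal uptake (11, and 2 more negative) and ribosomal proteins (1, and 7 more negative). For 24 against 14 h they were cell wall (11 and 2), RNA polymerase (5 and 0), pili (2 and 11), oxidative stress (1 and 7) and CRISPR-Cas (1 and 6). For 24 against 8 h they were ribosomal proteins (39 and 2), NADH dehydrogenase (14 and 0), histidine and aromatic synthesis (13 and 0), heat shock (12 and 2), RNA polymerase (4 and 0) and pili (1 and 11). With an estimated correlation no list was called for these changes, and the lowest adjusted p was 0.411, 0.573 and 0.488 for 14 against 8 h, 24 against 14 h and 24 against 8 h. For the nitrite reductase gene TSC_c17620 no such change was called (adjusted p = 0.179 for 14 against 8 h, 0.814 for 24 against 14 h and 0.26 for 24 against 8 h). Without the 3 replicates that stand apart 1390 genes were called for 14 against 8 h.

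The heating differences correlated across the 2461 genes at -0.19 between 8 and 14 h, 0.05 between 8 and 24 h and -0.02 between 14 and 24 h (Pearson), and genes are not independent replicates. Of the genes called at 8 and 14 h, 10 were higher and 15 lower at both, where independent lists would share 21.5 and 24.4, and 54 went from higher to lower and 58 from lower to higher, where they would share 21.4 and 24.6. At all 3 times 3 genes were higher and 6 lower, named here after their values were seen. The number that independent lists would share at all 3 times was not computed, so these counts show no constant response. The higher were TSC_c11860, the peptidase-related gene TSC_c17380 and TSC_c18870, of unknown function. The lower were rnpA, for the protein part of RNase P, the nitrite reductase gene TSC_c17620, the ferredoxin gene TSC_c14610 and the molybdopterin oxidoreductase gene TSC_c14620 next to it, the transporter gene TSC_c09660 and TSC_c06920, of unknown function.

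Over the convective growth course, 5 genes changed from 8 to 14 h and 1590 from 14 to 24 h (763 up, 827 down). The 5 were the cytochrome gene TSC_c17520, up 6.86-fold, and the sugar transporter genes TSC_c14820, TSC_c14810 and TSC_c14830 with the repressor gene TSC_c14800 beside them, down 5.87-fold, 5.66-fold, 4.62-fold and 7.97-fold. DESeq2 called 17 genes and a fit of the 5 libraries alone 39, among them 4 of the 5 and not TSC_c17520 (adjusted p = 0.104), and 113 had an unadjusted p under 0.05. Without the deeper convective 8 h library, or without convective 14 h replicate 2 or 3, edgeR called 0 genes, and without convective 14 h replicate 1 it called 1 and without the shallower library 3. Of the nitrate and anaerobic respiration list edgeR called 0 genes, and adjusted over the list alone 4 rose (camera adjusted p = 5.41e-05, and adjusted p = 0.628 with an estimated correlation). From 14 to 24 h thiG rose 174-fold and thiE 95.1-fold, the DNA primase gene TSC_c16910 111-fold and the pyruvate formate-lyase activating gene TSC_c23820 104-fold. The iron-binding and iron transport genes TSC_c23170 and TSC_c23180 fell 27.3-fold and 14.6-fold, TSC_c17620 17.6-fold and rplL 13.5-fold. The log2 change of TSC_c17620 was -4.14, or -4.75 without convective 24 h replicate 1. Heat shock genes rose in 15 of 28 cases and fell in 6 (camera adjusted p = 0.0165, and adjusted p = 0.384 with an estimated correlation), and ribosomal protein genes fell in 36 of 54 and rose in 3 (camera adjusted p = 0.00296, and adjusted p = 0.74 with an estimated correlation). Adjusted over the list alone these were 16 and 6, and 36 and 3. Also past camera's threshold were cell wall (2 up, 16 down), translation (2 and 19), ATP synthase (0 and 6), branched-chain synthesis (6 and 0), histidine and aromatic synthesis (4 and 17) and sulfur genes (14 and 3). With an estimated correlation no list was called over this interval, and the lowest adjusted p was 0.384.

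In microwave-heated cells 1277 genes changed from 8 to 14 h (630 up, 647 down) and 1308 from 14 to 24 h (669 up, 639 down). From 8 to 14 h thiG rose 633-fold, TSC_c11830 306-fold and thiE 272-fold, while argF fell 25.2-fold, narI 24.9-fold, narJ 21.9-fold and the nitrate transporter gene TSC_c17470 20.7-fold. The gene thiS went from 0.324 ± 0.562 to 199 ± 120 CPM, and its log2 change of 9.20 was 8.58 without microwave 8 h replicate 2 and 12.34 without replicate 3. All 18 NADH dehydrogenase genes rose, also adjusted over the list alone (camera adjusted p = 3.49e-09, and adjusted p = 0.382 with an estimated correlation). From 14 to 24 h the small heat shock protein genes TSC_c23100 and TSC_c20340 rose 308-fold and 215-fold, clpB 296-fold, from 188 ± 59.1 to 55800 ± 26000 CPM, and the heat-stable protein gene TSC_c20320 340-fold. Over the same interval TSC_c17610 fell 562-fold, from 7780 ± 1390 to 13.8 ± 5.01 CPM, the conserved domain gene TSC_c17750 402-fold, sdhB1, for succinate dehydrogenase, 305-fold and TSC_c23170 151-fold. Without microwave 24 h replicate 1 the log2 changes of TSC_c20320, TSC_c20340 and TSC_c23170 were 7.69, 6.85 and -7.98, against 8.41, 7.75 and -7.24, and that of sdhB1 was -7.57 without microwave 14 h replicate 3, against -8.25. Of 54 ribosomal protein genes 33 rose and none fell, and of 18 NADH dehydrogenase genes 17 fell and 1 rose, both also adjusted over the list alone (camera adjusted p = 0.000174 and 0.000433, and adjusted p = 0.656 and 0.59 with an estimated correlation). Also past camera's threshold from 8 to 14 h were ribosomal proteins (1 up, 27 down), heat shock (17 and 8), cytochromes (9 and 2), glutamate and arginine (5 and 14), CRISPR-Cas (7 and 0), sulfur (14 and 0) and metal uptake genes (18 and 3), and from 14 to 24 h heat shock (14 and 6), ATP synthase (0 and 6), branched-chain synthesis (8 and 0), mobile element (13 and 0) and regulator genes (40 and 11). With an estimated correlation no list was called over either interval, and the lowest adjusted p was 0.382 and 0.348. In a fit of the 14 and 24 h microwave libraries alone 634 genes were called.

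The authors' deposited tables list genes per time at an adjusted p of about 0.05, with highest values of 0.0545, 0.0541 and 0.055 at 8, 14 and 24 h. The authors' deposited table for 8 h holds 875 genes (479 higher in microwave, 396 lower), that for 14 h 1048 (543 and 505) and that for 24 h 1312 (678 and 634). Of them 216, 787 and 1131 were also called here, and 216, 785 and 1130 of these went the same way in the authors' deposited table. Independent lists would share 79.8, 428 and 722 genes. Of the authors' genes tested here, called or not, 869 of 873, 1026 of 1048 and 1304 of 1310 went the same way. The authors' lists and the calls here come from the same libraries.

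The titles call the libraries of a group biological replicates, and cultures were grown in triplicate vessels from which aliquots were taken. Nothing in the labels says whether the libraries of a group came from separate vessels, so the p-values measure the spread between these libraries. Nor do the labels say which libraries of different times share a vessel. Comparisons between times may therefore treat related libraries as independent.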

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

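Tests of mixing and depth in microwave 24 h replicate 1, all tests on the chromosome stretch and the test of reads outside genes were chosen after the result was seen. The interaction tests were planned. The predictions for the growth course, for rRNA reads and for a few high genes were written before their results were seen. The patterns weighed and the libraries left out in them were chosen after the data were seen.

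The heating difference differed between times by an interaction test, for 757 genes between 14 and 8 h, 1292 between 24 and 14 h and 997 between 24 and 8 h. From 8 to 14 h it became more positive for thiG by 9.33 ± 0.97 log2 units, for thiE by 8.1 ± 0.75 and for thiS by 9.04 ± 2.43, and more negative for narI (-6.85 ± 1.17), narJ (-6.84 ± 1.17) and TSC_c17470 (-6.46 ± 0.98). The thiG change was 8.69 without the deeper convective 8 h library. The thiS change rests on counts near 0 at 8 h: it was 5.34 without the deeper library (adjusted p = 0.991), 8.42 and 12.17 without microwave 8 h replicate 2 and 3, and 10.09 without convective 14 h replicate 1.

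From 14 to 24 h the difference became more positive for TSC_c02550 (6.57), azlC (5.91) and TSC_c02320 (5.67). It became more negative for TSC_c17750 (-7.84), thiG (-7.80) and the denitrification regulator gene TSC_c17540 (-7.75). Without convective 24 h replicate 1 the changes of TSC_c17750 and TSC_c17540 were -8.43 and -8.34, and that of TSC_c17540 was -6.82 without microwave 14 h replicate 3. From 8 to 24 h it became more positive for TSC_c10160 (6.27), TSC_c12630 (4.80) and the siroheme gene cysG (4.63), and more negative for hpaB (-6.27), hpaD (-6.07) and TSC_c10460 (-6.07). The change of TSC_c10160 was 7.19 without the deeper and 5.58 without the shallower convective 8 h library, and that of TSC_c12630 was 2.63 without microwave 24 h replicate 1. The call of hpaB was lost without the deeper library (adjusted p = 0.0561), and those of hpaD and TSC_c10460 without the shallower one (0.0528 and 0.0531).

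Reads outside annotated genes, which enter no comparison, were more frequent in microwave libraries by 3.56 per 100 gene counts as a mean over the 3 times (2-sided exact permutation p = 0.0055 over 4000 assignments within times). The differences were 2.91, 5.91 and 1.87 at 8, 14 and 24 h, with exact p = 0.1, 0.1 and 0.5, where 0.1 is the smallest possible at each time. Without microwave 24 h replicate 1 the 24 h difference was -0.44 and the mean over times 2.79, and without the shallower convective library the 8 h difference was 1.88.

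Microwave 14 h libraries had moved along the change that convective cells made later, from 14 to 24 h. On a scale from 0, the convective 14 h mean, to 1, the convective 24 h mean, over 932 rising and 935 falling genes, they lay at 0.33 ± 0.08 and microwave 8 h libraries at -0.06 ± 0.01 (SD, n = 3 each). Microwave 24 h libraries lay at 0.60 ± 0.15, where the scale's genes were chosen from convective libraries, so a value under 1 is no measure of delay. The tables argue against rRNA reads as the whole cause, since the correlation across genes between the microwave change from 8 to 14 h and the convective change from 14 to 24 h was 0.41, and 0.45 without the 3 libraries rich in unannotated rows. An earlier growth transition in microwave cultures may explain part of it and stays open, with the lowest library at 0.25. Whether it is the whole of the change stays open too, since 15.4% of the 895 genes called in both went opposite ways. Of 2461 genes, 240 lay above and 158 below all 8 convective libraries in every microwave 14 h library. Convective cells were not sampled between 14 and 24 h, so levels outside their range do not decide it either.

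Microwave 24 h replicate 1 stood apart from its group. The tables argue against low depth, with 3790053 gene counts, the most of its group. Its highest Spearman correlation to the other 2 was 0.91 once the highest genes were left out and 0.916 with them, so the remaining genes differed in rank too. A rank correlation hardly responds to a few genes, so this does not decide whether a few high genes took counts from the others. The tables argue against mixing with convective RNA, for which the genes high in convective cells would need shares from -2.95% to 17.1% (10th and 90th percentile). No biological explanation was tested.

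In a stretch of the chromosome from TSC_c15880 to TSC_c16670, 54237 bp with 77 tested genes, 76 were lower in microwave cells at 24 h by a median log2 difference of -3.14. Its ends were set by runs of genes each lower by at least 2 log2 units in this same comparison. Both values follow largely from that choice. Scaling moves all genes of a library alike. Against the other genes of the same library the stretch was -3.33 log2 units from its convective 24 h level. Since its genes were chosen for such a fall, this is no separate test of scaling. The median level alone does not decide complete loss of the stretch. The lowest microwave 24 h library had a median of 5.46 CPM, above the microwave 14 h mean of 3.80, but microwave 14 h replicate 2 was at 5.43. Before scaling the stretch held 0.0772% to 0.0939% of gene counts in microwave 24 h libraries. In microwave 14 h libraries it held 0.0771% to 0.0949%. From 14 to 24 h in microwave cells 15 of the 77 genes rose and 0 fell. With the unscaled shares, this argues against loss of the whole stretch from all cells. Loss in a share of the cells stays open. All 77 genes rose in convective cells from 14 to 24 h. This too follows in part from the choice, since the same convective 24 h libraries set the stretch. The rises ran from 3.08 to 6.26 log2 units (10th and 90th percentile), where more copies alone would raise the genes by a similar factor. Levels at 14 h were low, with library medians of 3.29 CPM on average, so this range does not decide it. More copies of the stretch or more transcription may explain the rise, which RNA counts cannot tell apart.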

How the results depend on the processing

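Alternatives that left out the 3 replicates standing apart or the 3 libraries rich in unannotated rows, blocked by column number or took symbols as the columns stand were chosen after the data were seen. Of 2497 values of named genes under all alternatives, 2342 kept their direction and side of the threshold, 88 lost a call, 26 gained one, 41 uncalled ones changed sign and 0 called ones reversed. Counts of called genes moved by over 1.5 times as follows, and where no reason is given the cause was not tested. At 8 h DESeq2 gave 344 and a fit of the compared libraries alone 844, against 225, where the coefficient of variation was 12.1% in that fit and 26.4% in the fit of all libraries. That fit gave 39 for convective 8 to 14 h, against 5, and 634 for microwave 14 to 24 h, against 1308. For convective 8 to 14 h DESeq2 gave 17, and leaving out the libraries rich in unannotated rows, which leaves fewer libraries, gave 0 in edgeR (113 at an unadjusted p under 0.05 with all libraries). Without the replicates standing apart 1531 genes were called at 14 h and 1390 for 14 against 8 h. A minimum log2 change of 1, a stricter rule, gave 135, 506 and 822 at 8, 14 and 24 h, 972 for convective and 676 for microwave 14 to 24 h and 739 for microwave 8 to 14 h. Leaving out 1 library gave 54 to 121 genes at 8 h and 0 to 3 for convective 8 to 14 h, where a lone convective 8 h library is assumed to vary like other groups. The other comparisons stayed within 1.5 times of their counts.

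Lists past the threshold numbered 0 at 8, 14 and 24 h with an estimated correlation, where the preset correlation in limma's camera gave 5, 5 and 6. At 14 h a fit of the compared libraries alone gave 8, fry 17 and leaving out the replicates standing apart 8, and at 24 h fry gave 21, where fry asks another question than camera and its counts are not counts of the same calls. Leaving out 1 library gave 3 to 6 lists at 8 h. With the title number as a replicate block 944 genes were called at 14 h and 1296 at 24 h. After the group mean of each gene was subtracted from log CPM, the deviations of same-numbered libraries of both heating modes were correlated. These correlations were -0.21 to -0.04 at 14 h and -0.17 to -0.10 at 24 h. By these deviations 0 of 12 libraries correlated best with its own number in the other heating mode. With the number taken as a vessel within each heating mode, 1525 genes were called for convective 14 to 24 h. For microwave 8 to 14 h and 14 to 24 h they were 1175 and 1199, and for the change of the heating difference from 14 to 24 h 1212. With the column number as a replicate block 167 genes were called at 8 h, without TSC_c13200 (adjusted p = 0.056), TSC_c13640 (0.06), nuoA (0.0619) and nuoB (0.0815). Scaling with RLE shifted the median of all genes by 0.101 log2 units for 14 against 8 h. Not run were the correction for GC content and length, its block version, for want of a genome, and the title-number block for comparisons with convective 8 h, whose columns carry other numbers.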

Other observations

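Searches for runs of neighbouring genes were chosen after the results were seen. The splits of the libraries were planned.

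Neighbouring genes often changed together. Runs of at least 5 adjacent called genes, each changed by at least 2 log2 units one way, numbered 1, 4 and 11 at 8, 14 and 24 h, where gene orders shuffled 1000 times gave at most 0, 0 and 1. Shuffling takes genes as independent, which neighbours transcribed together are not, so it gives no test of heating. At 24 h 8 genes of siroheme and sulfate assimilation, from cobB through sat, cysH and cysG to TSC_c11790, were higher by a median of 3.76 log2 units (chromosome 1112582 to 1120270). So were 6 ribosomal protein genes from rpsC to rplD (median 2.27) and 6 genes from dnaK to the heat-stable protein gene TSC_c20320 (2.40). Next to transposase genes, 14 genes from TSC_c12530 to TSC_c12660 were higher by a median of 4.90, and the values of TSC_c12600, TSC_c12630 and TSC_c12640 among them fell to 2.94, 3.23 and 2.56 without microwave replicate 1.

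At 14 h 6 genes from the chaperone gene htpG to TSC_c03480, with a molybdopterin oxidoreductase and an iron permease between them, were higher by a median of 2.55 log2 units. Another 6, from the iron-sulfur assembly gene TSC_c17400 to the hemerythrin gene TSC_c17450, were higher by a median of 2.66 and lie directly beside the nitrate reductase run from TSC_c17460 to TSC_c17520, which was lower by a median log2 difference of -5.49. Of 8 plasmid genes tested, edgeR called 0 at 8 h, 3 higher and 1 lower at 14 h, and 3 lower at 24 h. Over all genes at 8 h 586 had an unadjusted p under 0.05 and DESeq2 called 344.

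Other splits of the same libraries were fitted for each count of called genes. With 10 splits per comparison they are too few for a share under 0.05, and 1 of the 10, the real split, reached the real count each time. The real count and the highest other were 1006 and 0 at 14 h, 1357 and 96 at 24 h, 1590 and 0 for convective 14 to 24 h, 1277 and 0 for microwave 8 to 14 h and 1308 and 312 for microwave 14 to 24 h. For the change of the heating difference from 14 to 24 h, 1 of 100 relabellings within times, the real one, reached 1292 genes and the highest other gave 794. A share of 1 in 100 is the smallest that these draws can give. Relabelling also takes the libraries as independent, which the labels do not settle.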
